A study of Homo sapiens with 14 samples.

How the data were processed

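RNA from left ventricle of 14 human donors was sequenced, 1 library per donor: 7 from children with failing hearts (idiopathic dilated cardiomyopathy, per the series labels) and 7 controls. The column headers name all 14 libraries pediatric, controls included. Groups were taken from the sample titles, since the diagnosis label carries the same value on all 14 libraries. The labels name a mirVana kit for extraction and an Illumina TruSeq kit for the libraries. TopHat2, Cufflinks and the genome build hg19 are named in the submitters' processing notes. Versions and the gene annotation are not given in the sources used here. The deposited table holds FPKM (fragments mapped to a gene, relative to its transcript length and to all mapped fragments) for each library, made by the authors, per the file headers. Whether a further scaling between libraries was applied is not stated.

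The table lists 7031 genes. The larger of the 2 group medians was at least 9.05 FPKM for each of them, so genes of low level in both groups had been left out by a filter that is not stated. A gene low in 1 group is therefore listed only if it is high in the other: 425 tested genes are listed through the failing group only (43 called) and 397 through controls only (40 called). Members of a list that are low in both groups are missing, so the direction of a list with many missing members depends in part on this filter. Counts of reads were not used here and depth per library is unknown, so no counting interval or detection floor is given. The FPKM values summed to between 539493 and 701423 per library over the listed genes. All per-sample columns of the table were used. Genes on the Y chromosome and XIST (7 genes) were left out of all tests, leaving 7024.

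The table's symbols were looked up in a RefSeq table for the assembly GRCh38.p14, which differs from the authors' build, so it served only for names and gene order; 6990 symbols were found. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend=TRUE), with group as the only term and Benjamini-Hochberg adjustment over the 7024 genes at a threshold of 0.05. A minimum mean of 1 FPKM removed no gene. Fold changes are on the log2(FPKM + 1) scale, failing over control, which understates changes of low genes. P-values of single genes measure the spread between donors. Camera at a preset correlation compares the genes of a list with the other genes and rests on the assumed correlation. None of its list calls passed with an estimated one. Such a loss need not come from correlation between members: for the Wnt list the estimate was 0.00944 against a preset of 0.01. On 5 simulated tables of 7024 genes made for this comparison, each with 200 changed genes, the fit recovered 31.0% of genes changed by 1.5-fold, 72.2% of those changed by 2-fold and 96.7% of those changed by 4-fold, with 4.32% false among the called genes. The simulated noise was normal, independent between genes and equally wide in both groups. In the data, members of many lists were correlated and controls spread more widely, so these rates may not hold there.

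Before the data were examined, 26 gene lists and 16 lists of cell type markers were written from textbook knowledge (691 genes, 453 of them in the table). The 33 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists, with camera at an estimated correlation and fry beside it. The 10 single genes, the rule for named genes and the alternatives were also fixed before the data were examined. Named genes are the 10 fixed genes, of which 1 is not reported here; the 8 largest rises and 8 largest falls among called genes whose failing values lay beyond the control median in at least 6 of 7 failing libraries; and, for lists past the set test or with at least 3 called members, the 3 called members with the largest change, or, with fewer called, those and the members with the smallest p up to 2. Called members are named for the other lists that have 2 or fewer. For the fixed genes an exact two-sided permutation test over 3432 arrangements was added, whose smallest possible p is 0.000583.

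The donor numbers in the titles ascend in 2 runs, and the column headers spell their prefix in 2 ways along the same split. These runs are called set 1 (replicates 1 to 3 of both groups, 6 libraries) and set 2 (replicates 4 to 7 of both groups, 8 libraries) and were treated as a possible batch. Alternatives covered pseudocounts of 0.1 and 5, other filters, median-ratio and quantile scaling, robust moderation, array weights, a term for the set, each set alone, each library left out in turn and other thresholds. For these fits the number of called genes is given as a percent of the 7024 genes. A change of sign, or for lists of the direction of the set test, was counted as a reversal whether or not the value had passed the test. Alternatives chosen after seeing the data were values below 0.001 set to missing, small RNA genes left out, a minimum mean of 20 FPKM, the set term without control replicate 5, the fits without control replicates 2 and 3 or 3 and 5, and only genes with both group medians at 9.05 FPKM or more.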

Results

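Left ventricular transcriptomes were compared between 7 children with dilated cardiomyopathy in heart failure and 7 pediatric controls. The comparison asks which transcripts differ in the failing pediatric ventricle. Expression was given as FPKM for 7031 genes, and the depth of the libraries is unknown.

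The failing ventricles had lost most transcript of MYH6, the fast alpha isoform of cardiac myosin heavy chain. Its mean fell from 1368 ± 567 FPKM in controls to 97.5 ± 26.2 in failing hearts (SD, n = 7 each), a log2 fold change of -3.72 (SE 0.25, limma adjusted p = 5.8e-07) with no overlap between groups. ATP2A2, the calcium pump of the sarcoplasmic reticulum, fell from 1534 ± 544 to 750.1 ± 115 FPKM (log2 fold change -0.95, SE 0.23, adjusted p = 0.0271). Its log2 fold change was -0.39 in set 1 and -1.38 in set 2. The call ended without control replicates 2, 6 or 7 or failing replicates 2, 4 or 6 (adjusted p up to 0.0625). The exact permutation test gave p = 0.0041 for ATP2A2 and p = 0.000583 for MYH6 (0.0184 and 0.0052 after adjustment over the fixed genes). SERPINA3, an acute phase protease inhibitor, fell from 91.4 ± 27.1 to 8.61 ± 4.43 FPKM (log2 fold change -3.33, SE 0.27, adjusted p = 3.9e-06). APOA1, the main apolipoprotein of high-density lipoprotein, rose from 14.1 ± 11.2 to 122 ± 75.3 FPKM (log2 fold change 2.98, SE 0.42, adjusted p = 0.0020).

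The other fixed genes did not pass the test over all genes. MYH7, the slow beta myosin heavy chain, stood at 2608 ± 1169 FPKM in controls and 3669 ± 470 in failing hearts (log2 fold change 0.60, SE 0.23, adjusted p = 0.144, exact permutation p = 0.0291 before and 0.0874 after adjustment over the fixed genes). Without control replicate 1 its log2 fold change was 0.77 and past the threshold (adjusted p = 0.0257). The natriuretic peptide genes NPPA and NPPB, ventricular stress markers, varied widely within both groups. NPPA averaged 497 ± 589 FPKM in controls and 4060 ± 4462 in failing hearts (log2 fold change 2.71, SE 1.09, adjusted p = 0.161, exact permutation p = 0.0548); its log2 fold change was 0.16 in set 1. It was past the threshold in set 2 (4.62, adjusted p = 0.0336) and without failing replicate 3 (3.67, adjusted p = 0.0225). NPPB averaged 2018 ± 3232 FPKM in controls and 1570 ± 901 in failing hearts, while its log2 fold change, which gives single high libraries less weight, was 0.73 (SE 1.23, adjusted p = 0.771). That value was -1.83 in set 1 and 2.66 in set 2 (adjusted p = 0.765 and 0.122) and 0.19 to 1.69 with 1 library left out. Control replicates 2 and 3, with 8727 and 3761 FPKM of NPPB, lay above each failing library. The beta-1 adrenergic receptor gene ADRB1 (-0.11, SE 0.27), the fibrillar collagens COL1A1 (0.19, SE 0.46) and COL3A1 (-0.14, SE 0.48) and the matricellular gene POSTN (-0.06, SE 0.67) had adjusted p of 0.847, 0.851, 0.895 and 0.971.

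**Figure D1:**
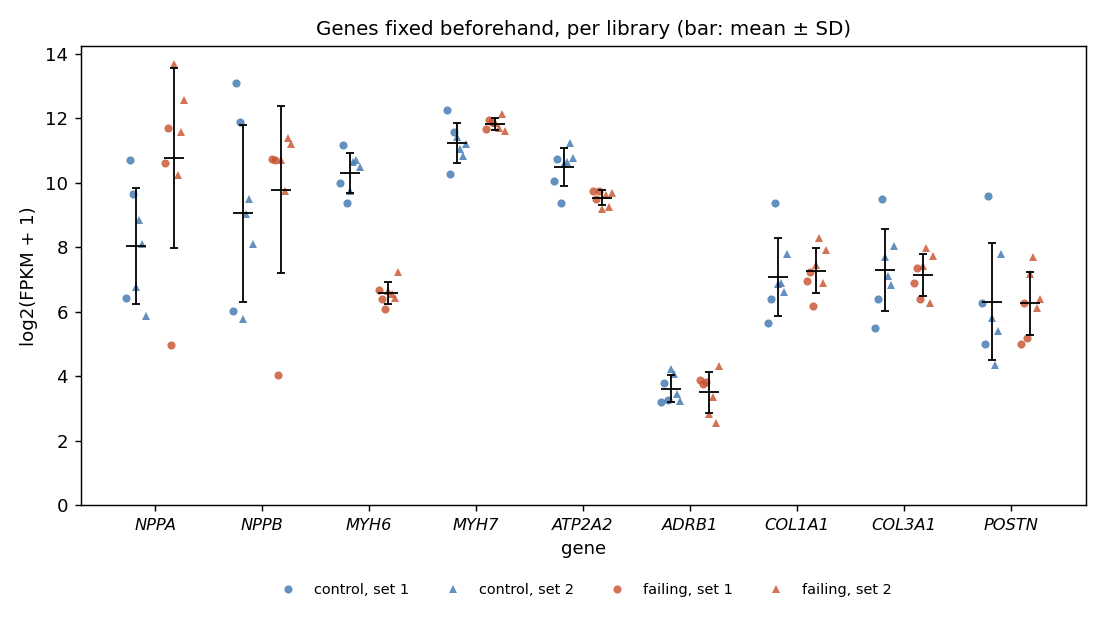
Levels of the fixed genes as log2(FPKM + 1) on the vertical axis for each library, controls in blue and failing hearts in orange, with circles for set 1 and triangles for set 2; black bars give the mean and SD of 7 libraries. MYH6 separates the groups completely, while NPPB in control replicates 2 and 3 lies above the failing libraries.

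Over all genes, 320 of 7024 (4.56%) differed between failing and control ventricles by limma at an adjusted p under 0.05, 162 higher and 158 lower in failing hearts, against 1498 genes at an unadjusted p under 0.05. Of these, 140 changed by at least 2-fold, 70 in each direction. The groups did not overlap for 101 genes (1.44%, against 0.0583% by chance), 83 of them called. With a term for the set, 412 genes were called, among them all 320. Set 1 alone gave 4 genes and set 2 alone 52, of which 50 had the same sign in set 1, against 70.3% of all genes. A limma test of whether the change from control to failing differed between the sets called 0 genes (198 at an unadjusted p under 0.05). The called share of 4.56% became 7.13% without control replicate 1, 2.49% without control replicate 2, 2.31% without control replicate 6, and 2.61%, 2.82%, 2.52%, 2.26% and 2.38% without failing replicates 2, 3, 5, 6 and 7.

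The largest rises after APOA1 included Wnt pathway genes and a thyroid hormone binding protein. WNT9A, a Wnt ligand, rose by a log2 fold change of 2.47 (SE 0.48, adjusted p = 0.0111), and the secreted Wnt modulators SFRP1 and SFRP4 by 2.21 (SE 0.38) and 2.10 (SE 0.50). CRYM, which binds thyroid hormone, rose from 35.2 ± 21.5 to 167 ± 19.2 FPKM (SD, n = 7 each) without overlap. C19orf51 (2.46), HFE2, a hemojuvelin gene of iron regulation (2.37), and PI16, a gene of fibroblasts (2.34), were the others. The largest falls after MYH6 were PLA2G2A, a secreted phospholipase (-3.37, SE 0.62), CMTM5 (-3.34, SE 0.55), SERPINA3, the secreted phosphoprotein SPP1 (-3.16, SE 0.71), TUBA3D (-2.78, SE 0.41), KCNIP2, a subunit of the transient outward potassium channel (-2.67, SE 0.70), and HOPX, a homeodomain regulator of cardiac genes (-2.60, SE 0.62). TUBA3D is uncertain, since near-identical tubulin copies can share its reads. The table holds WNT9A, C19orf51, HFE2, SFRP1 and SFRP4 only through the failing group. It holds PLA2G2A, CMTM5, SERPINA3, SPP1, TUBA3D and HOPX only through controls, so the ranking depends in part on the filter. KCNIP2 had a log2 fold change of -0.73 in set 1 and -4.12 in set 2, and was called in 4 of the 14 fits that left out 1 library. PI16 was called in 7, SFRP4 in 8 and HOPX in 9 of them. KCNIP2 lost its call with robust moderation (adjusted p = 0.0606), array weights (0.0726) and the set term without control replicate 5 (0.0649). With array weights PI16 (0.0633) and SFRP4 (0.0519) were not called either.

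**Figure D2:**
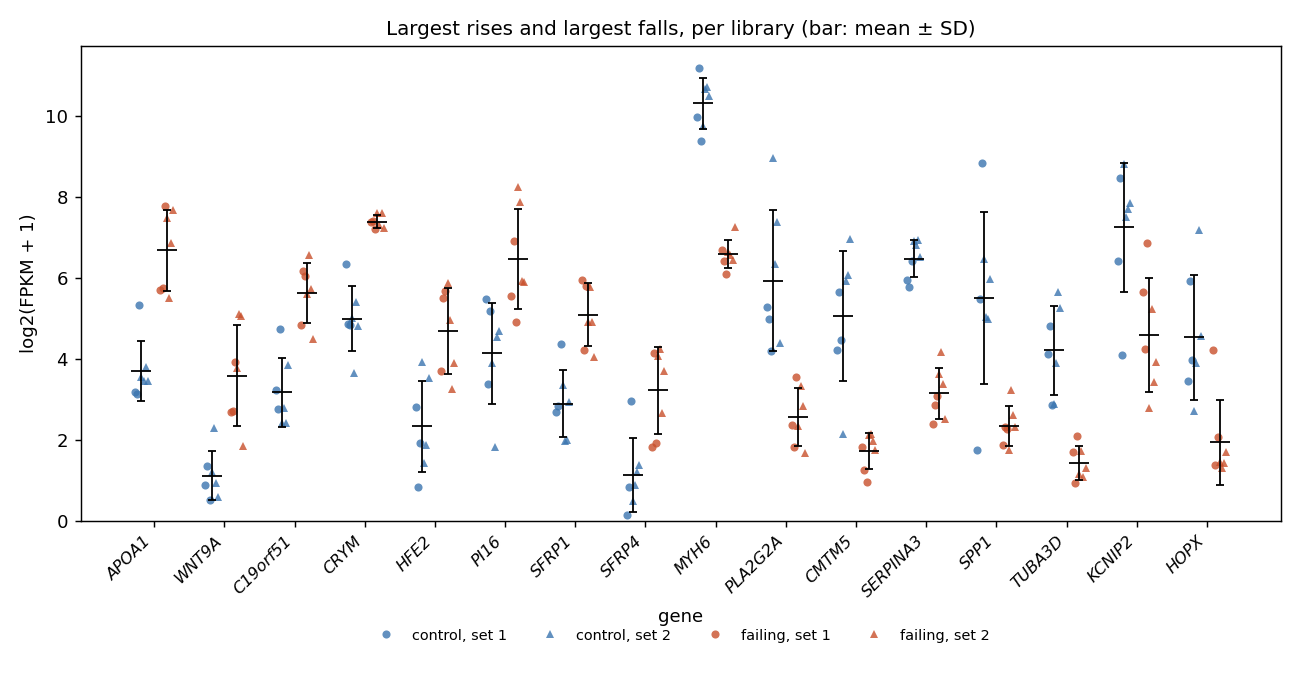
Levels of the 8 genes with the largest rise (left) and the 8 with the largest fall (right) as log2(FPKM + 1) on the vertical axis for each library, in blue for controls and orange for failing hearts, with circles for set 1 and triangles for set 2; black bars give mean and SD of 7 libraries. APOA1, CRYM, MYH6 and SERPINA3 are among the genes whose groups do not overlap.

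Among contractile genes, 5 of 20 measured sarcomere genes rose, 1 fell and 14 did not pass the test (adjusted over the list alone, 5 rose and 1 fell). MYOM2, of the M-band, rose by 1.37 (SE 0.27) on the log2 scale and cardiac troponin I, TNNI3, by 1.06 (SE 0.16), against the fall of MYH6. The list passed camera (adjusted p = 0.0190; adjusted p = 0.415 with an estimated correlation), with medians of 0.14 in set 1 and 0.19 in set 2. Its call ended with quantile normalization (median 0.092, adjusted p = 0.178) and array weights (0.099, adjusted p = 0.0556). MYL2 was called in 5 of the 14 fits that left out 1 library, KCNH2 in 9 and GATA6 in 11. Quantile normalization took MYL2 from 0.92 to 0.50 (adjusted p = 0.0991), and array weights also ended its call (0.0658). Of 13 measured genes of the fetal and stress programme none passed (camera adjusted p = 0.267; 0 adjusted over the list alone), while the list passed camera in set 2 (median 0.81, adjusted p = 0.0334) and without controls 2 and 3 (0.72, adjusted p = 0.0454). These became adjusted p = 0.506 and adjusted p = 0.415 with an estimated correlation. Among 15 calcium handling genes ATP2A2 alone fell (camera adjusted p = 0.825; 1 adjusted over the list alone), where the median of 0.07 and the mean of -0.05 differ in sign. The ion channel list had KCNIP2 and the repolarising channel gene KCNH2 (-0.59, SE 0.14) lower among 10 measured (camera adjusted p = 0.267; 2 adjusted over the list alone), and none of 18 adrenergic and cAMP signalling genes passed, before or after adjusting over the list alone (camera adjusted p = 0.825), with a median of -0.06 and a mean of 0.0016. With 1 library left out the adrenergic median ran from -0.094 to 0.040. Of 16 cardiac transcription factors GATA6 rose (0.61, SE 0.14; camera adjusted p = 0.825; 1 adjusted over the list alone), with a median of -0.08 and a test direction upward. Cardiomyocyte markers rose in 2 of 10 cases (TNNI3 and the ventricular light chain MYL2, 0.92, SE 0.23) and fell in 1, MYH6 (camera adjusted p = 0.285; the same 2 and 1 adjusted over the list alone), with a median of 0.17 and a mean of -0.05.

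Of 22 measured fatty acid oxidation genes 20 had positive fold changes, with a median of 0.28 (0.16 in set 1, 0.33 in set 2). CPT1B, the carnitine palmitoyltransferase of muscle, rose by 1.04 (SE 0.20), and 21 did not pass (1 adjusted over the list alone). The CPT1B value was 0.48 in set 1 and 1.45 in set 2. MLYCD, malonyl-CoA decarboxylase, had a value of 0.73 (SE 0.24, adjusted p = 0.0991), with a call in set 2 (1.24, adjusted p = 0.0483) and without failing replicate 1 (0.87, adjusted p = 0.0485). The list passed camera (adjusted p = 0.0010; adjusted p = 0.477 with an estimated correlation). Of 21 glycolysis genes 3 fell (3 adjusted over the list alone): the glucose transporter SLC2A1 (-1.67, SE 0.25), lactate dehydrogenase LDHA (-1.61, SE 0.25) and enolase ENO1 (-1.03, SE 0.25), with camera adjusted p = 0.0186 and adjusted p = 0.415 with an estimated correlation. The glycolysis median was 0.0090 in set 1 and -0.36 in set 2. The list was not called in set 1 (adjusted p = 0.895) or without control replicates 1 (0.0518) and 4 (0.0538). ENO1 was called in 7 of the 14 fits that left out 1 library. None of 30 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.131) or 18 citrate cycle genes (camera adjusted p = 0.388) passed, with 0 adjusted over the list alone in both. In set 1 both lists passed camera (medians 0.20 and 0.25, adjusted p = 7.3e-05 and 0.0016; adjusted p = 0.648 for each with an estimated correlation). The oxidative phosphorylation list also passed without failing replicates 5 (median 0.16, adjusted p = 0.0260) and 6 (0.13, adjusted p = 0.0408), with adjusted p = 0.715 and adjusted p = 0.714 with an estimated correlation.

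Of 12 measured NF-kB, cytokine and acute phase genes 4 fell and 8 did not pass (7 fell adjusted over the list alone). Beside SERPINA3, the calgranulins S100A9 and S100A8, abundant in neutrophils, fell (-2.47, SE 0.33, and -2.05, SE 0.54), and the oncostatin M receptor gene OSMR was the fourth. The list passed camera (adjusted p = 9.9e-05; adjusted p = 0.415 with an estimated correlation), with medians of -1.44 and -1.90 in sets 1 and 2. Control replicate 5 had a mean of 7.13 over this list against 4.36 to 5.18 in the other controls, and without it the median moved from -1.82 to -1.13 (adjusted p = 0.0025). The table holds 7 of the 12 genes, and 3 of the 4 called, only through the control group; over the other 5 the median was -0.20 (adjusted p = 0.161), a choice that also removes large falls. S100A8 was called in 4 of the 14 fits that left out 1 library, S100A9 in 14 and CD14 in 10, and S100A8 lost its call with robust moderation (adjusted p = 0.0536). Of 7 macrophage markers 4 fell (5 adjusted over the list alone), among them the scavenger receptor CD163 (-1.95, SE 0.38), the hyaluronan receptor LYVE1 (-1.80, SE 0.28) and the endotoxin co-receptor CD14 (-1.41, SE 0.33), while the colony stimulating factor receptor CSF1R had a value of -0.03 (SE 0.33). That list passed camera (adjusted p = 3.7e-04; adjusted p = 0.415 with an estimated correlation), with medians of -1.06 and -1.23 in the sets. Both measured neutrophil markers were the calgranulins.

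Complement genes had 1 of 13 lower (5 adjusted over the list alone), the membrane regulator CD59 (-0.84, SE 0.13), while C1R had -0.83 (SE 0.29, adjusted p = 0.112), with a call without control replicate 2 (-1.06, adjusted p = 0.0271). For the list camera gave adjusted p = 0.0257 and adjusted p = 0.550 with an estimated correlation. From a median of -0.59, the call ended in set 1 (-0.27, adjusted p = 0.572), without control replicates 1 (-0.49, adjusted p = 0.0726) and 4 (-0.38, adjusted p = 0.210) and without failing replicate 7 (-0.49, adjusted p = 0.0529). Of 20 heat shock and unfolded protein response genes 18 had negative fold changes and 1 fell (2 adjusted over the list alone), the small heat shock protein gene HSPB7 (-0.76, SE 0.15). XBP1, a transcription factor of the unfolded protein response, had -0.71 (SE 0.20, adjusted p = 0.0575). It was called with the set term (adjusted p = 0.0484), with array weights (0.0248) and without control replicates 1 (-0.82, adjusted p = 0.0206) or 3 (-0.78, adjusted p = 0.0487). Camera gave adjusted p = 0.0012 for that list and adjusted p = 0.559 with an estimated correlation. That call ended in set 1 (median -0.26, adjusted p = 0.198) and without control replicate 5, where the median moved from -0.50 to -0.22 (adjusted p = 0.0789). Control replicate 5 had the highest mean level over the list of the 14 libraries (8.43 on the log2 scale). None passed among 5 metallothioneins (median -1.31, camera adjusted p = 0.0529), 11 interferon genes (0.378), 7 MHC class II and antigen presentation genes (0.705), 11 glucocorticoid-responsive genes (0.944; median 0.18, mean -0.12) and 11 p53 genes (0.825; median 0.06, mean -0.11), with 0 in each adjusted over the list alone. The metallothionein list passed camera in set 2 (median -1.52, adjusted p = 0.0343), with a pseudocount of 0.1 (-1.43, adjusted p = 0.0476) and without controls 2 and 3 (-1.73, adjusted p = 0.0046). It also passed in 7 of the 14 fits that left out 1 library (control replicates 2, 3 or 4 or failing replicates 3, 4, 5 or 6; medians -1.64 to -1.30). In none of these did it pass with an estimated correlation (adjusted p = 0.408 to 0.605 with an estimated correlation). The interferon list passed in set 1 (median 0.56, adjusted p = 0.0032) and without control replicate 5 (0.44 against 0.16, adjusted p = 0.0210), with adjusted p = 0.643 and adjusted p = 0.516 with an estimated correlation. It also passed camera without controls 3 and 5 (median 0.57, adjusted p = 0.0011; adjusted p = 0.329 with an estimated correlation). So it did with the set term but without control replicate 5 (0.40, adjusted p = 0.0273; adjusted p = 0.542 with an estimated correlation). With 1 library left out the interferon median ran from -0.051 to 0.44. Among 16 immediate early genes KLF2, a flow-responsive factor of endothelium, rose by 0.85 (SE 0.22; camera adjusted p = 0.649; 1 adjusted over the list alone) and was called in 6 of the 14 fits that left out 1 library.

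Of 26 collagen and fibrosis genes SFRP4 rose and COL6A3, a collagen VI chain, fell with a log2 fold change of -0.998 (SE 0.23), and 24 did not pass (camera adjusted p = 0.411; 1 and 1 adjusted over the list alone). Without control replicate 3 that list passed camera, with a median of 0.48 against 0.15 (adjusted p = 0.0208), as it did without controls 2 and 3 (0.41, adjusted p = 0.0422) and 3 and 5 (0.45, adjusted p = 0.0154). These became adjusted p = 0.703, 0.932 and 0.666 with an estimated correlation. Among 9 matrix proteases and inhibitors TIMP1, the metalloproteinase inhibitor, fell (-1.64, SE 0.44) and MMP19 (-1.50, SE 0.37), with 3 lower adjusted over the list alone; camera gave adjusted p = 0.0463 and adjusted p = 0.415 with an estimated correlation. That call ended with the set term (adjusted p = 0.0571), with median-ratio (0.0533) and quantile scaling (0.0698), in set 2 (median -0.28, adjusted p = 0.116), over members with both group medians at 9.05 FPKM or more (-0.48, adjusted p = 0.128), at a minimum mean of 20 FPKM (0.261) and in 7 of the 14 fits that left out 1 library (without control replicates 1, 5 or 6 or failing replicates 1, 3, 6 or 7; adjusted p up to 0.0926, and a median of -0.35 without control replicate 5). TIMP1 was called in 3 of those 14 fits, MMP19 in 6, COL6A3 and LTBP4 in 11. Of 8 measured Wnt genes WNT9A, SFRP1 and SFRP4 rose (4 adjusted over the list alone), with camera adjusted p = 0.0026 and adjusted p = 0.130 with an estimated correlation, and medians of 0.48 and 0.82 in the sets. The estimated correlation of this list was 0.00944, close to the preset 0.01, so correlation between members does not explain that loss. The Wnt call ended at a minimum mean of 20 FPKM, where the median moved from 0.62 to 0.045 (adjusted p = 0.261). Of the 29 genes of the list 8 are in the table, and WNT9A, SFRP1 and SFRP4 have control medians of 0.915, 6.15 and 0.846 FPKM, so the table holds them only through the failing group. Over the 4 members with both group medians at 9.05 FPKM or more the median was -0.0026 (adjusted p = 0.675), a choice that also removes large rises. SFRP1 and SFRP4 are secreted inhibitors or modulators of the pathway. LTBP4, a binding protein of latent TGF-beta, rose by 1.28 (SE 0.30) among 14 TGF-beta and BMP genes (camera adjusted p = 0.0512; 3 higher and 1 lower adjusted over the list alone). With the set term the list passed camera (adjusted p = 0.0478), as it did with a pseudocount of 0.1 (0.0476) and in set 2 (median 0.66 against 0.42, adjusted p = 0.0024). It also passed without control replicates 3, 5 or 6 or failing replicates 1 or 3 (medians 0.41 to 0.48). In none of these did it pass with an estimated correlation (adjusted p = 0.263 to 0.544 with an estimated correlation). Of 6 measured cell cycle genes the D cyclins CCND1 and CCND2 rose by 1.18 (SE 0.24) and 0.89 (SE 0.18), with camera adjusted p = 0.120 and 2 adjusted over the list alone. The cell cycle list passed at a minimum mean of 20 FPKM (median 0.52 against 0.12, adjusted p = 0.0454) and without controls 2 and 3 (0.29, adjusted p = 0.0292), with adjusted p = 0.327 and adjusted p = 0.316 with an estimated correlation. With 1 library left out its median ran from -0.00060 to 0.21, and it passed in 0 of these 14 fits. FGF1 rose by 1.62 (SE 0.33) among 15 hypoxia and angiogenesis genes (camera adjusted p = 0.825; 1 higher and 1 lower adjusted over the list alone), and none of 25 cytosolic ribosomal protein genes passed (0.666; 0 adjusted over the list alone).

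Markers of other cell types gave smaller counts. LYVE1, also a lymphatic marker, was the one called gene among 3 lymphatic markers (2 lower adjusted over the list alone), with PDPN at -0.60 (SE 0.23, adjusted p = 0.142; called in set 2, -1.14, adjusted p = 0.0483). For the lymphatic list camera gave adjusted p = 0.0463 and adjusted p = 0.415 with an estimated correlation, and the median was 0.13 in set 1 and -1.14 in set 2. That call ended with a pseudocount of 5, with median-ratio (0.0533) and quantile scaling (0.0626), with array weights (0.0556) and in 8 of the 14 fits that left out 1 library. The table holds 2 of the 3 markers only through the control group. PI16 rose among 8 fibroblast markers (camera adjusted p = 0.153; 2 adjusted over the list alone), a list that passed without failing replicate 1 (median 0.69 against 0.46, adjusted p = 0.0476; adjusted p = 0.565 with an estimated correlation), and CGNL1 by 1.16 (SE 0.28) among 2 endocardial markers, which were too few for a set test (1 adjusted over the list alone). CGNL1 was called in 9 of the 14 fits that left out 1 library. In these fits the fibroblast median ran from 0.26 to 0.69. None passed among 8 vascular endothelial markers (camera adjusted p = 0.378; 0 adjusted over the list alone), 5 atrial markers (0.246; 1 adjusted over the list alone) and 9 pericyte and smooth muscle markers (0.825; 1 adjusted over the list alone). With the set term the endothelial marker EGFL7 (0.42, adjusted p = 0.0439), the smooth muscle myosin gene MYH11 (1.02, adjusted p = 0.0444) and the mesothelial marker KRT8 (-1.09, adjusted p = 0.0461) were called. Adipocyte, Schwann and neural, and erythroid markers, with 2 measured each, and mesothelial markers, with 1, had no called gene over all genes, and adjusted over the list alone 2 Schwann and neural and 1 mesothelial marker were lower. T and NK cell, B and plasma cell, and mast cell markers had 0 measured members. Of the 33 tested lists 10 passed camera, 0 passed with an estimated correlation, and 5 passed fry (Wnt, glycolysis, NF-kB and acute phase, macrophage and lymphatic).

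**Figure D3:**
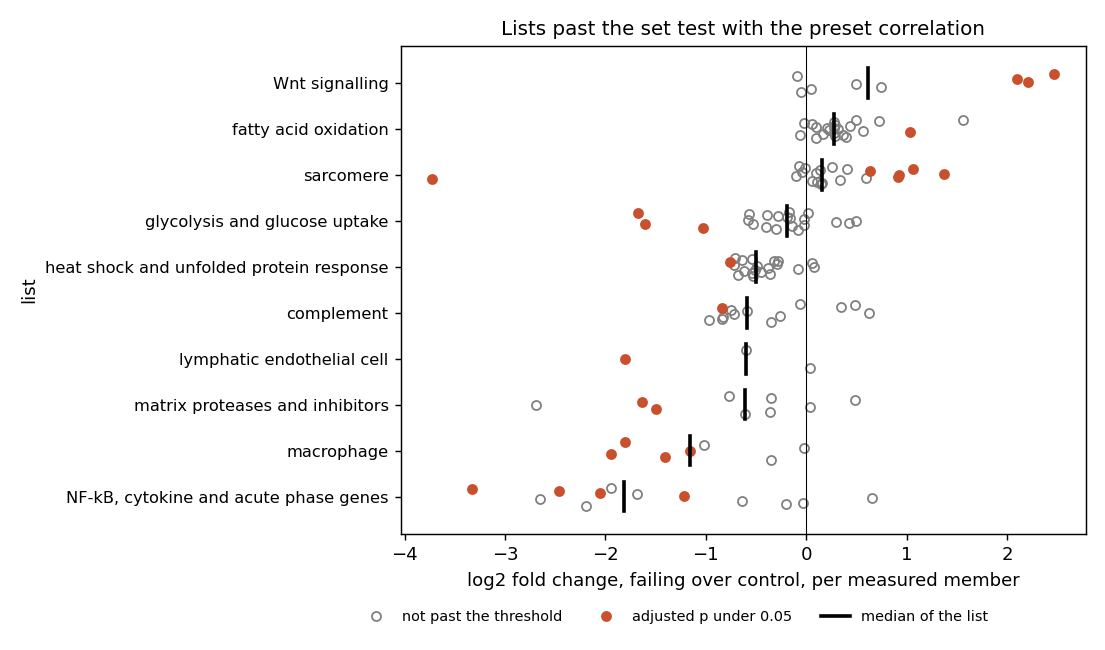
Log2 fold change of failing over control (horizontal axis) for each measured member of the 10 lists that passed camera with the preset correlation; filled orange points have an adjusted p under 0.05, open points do not, and black bars mark the median of each list. Medians run from -1.82 for NF-kB, cytokine and acute phase genes to 0.62 for Wnt signalling.

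The first principal component held 25.7% of the variance and separated the groups, with controls between -51.8 and 3.98 and failing libraries between 10.1 and 24.4. The second held 16.5% and separated set 1 (each library below 0) from set 2 (each above 0). In the fit with the set term 372 genes differed between sets, 234 higher in set 2.

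**Figure D4:**
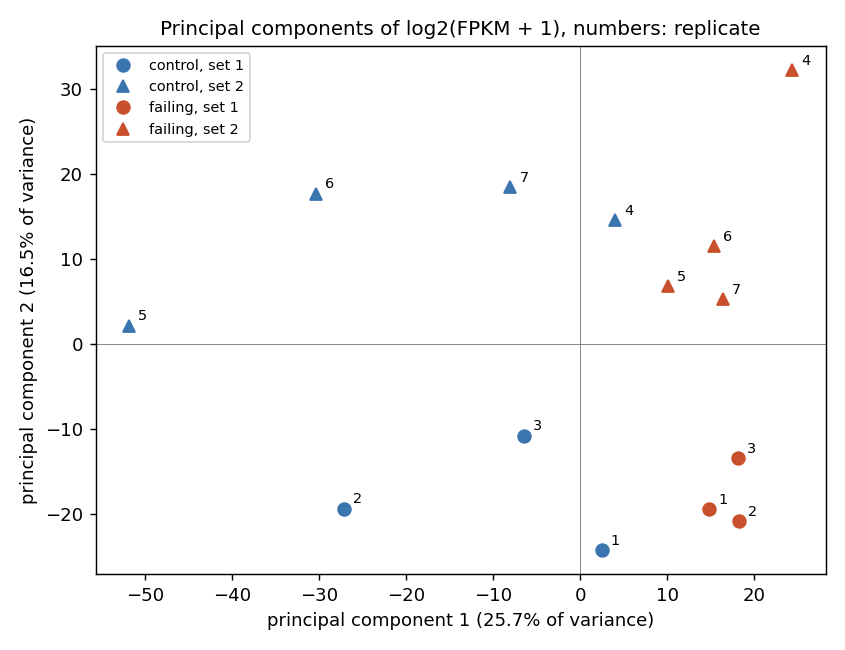
The first (horizontal) and second (vertical) principal components of log2(FPKM + 1) over 14 libraries, numbered by replicate, in blue for controls and orange for failing hearts, with circles for set 1 and triangles for set 2. Groups separate along the first component and sets along the second, and control replicate 5 lies farthest out at -51.8.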

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

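Of the tests below, the one for exchanged labels was written before its result was seen; the test for atrial tissue was chosen only afterwards. Among 86 genes and list means, each checked in both groups of 7 libraries, 11 checks had 1 library far from the rest of its group, or 6.4%; chance gives about 1 in 20. All values are log2(FPKM + 1). In failing replicate 3, NPPA was 4.98 (10.2 to 13.7 in the other 6), NPPB 4.04 (9.74 to 11.4) and the mean of the fetal and stress programme 8.07 (9.31 to 10.2). NPPA and NPPB are members of that programme, so these checks are not independent. In failing replicate 1, HOPX was 4.22 (1.29 to 2.06), the mean of the cell cycle list 5.08 (4.5 to 4.74) and that of MHC class II and antigen presentation 6.53 (5 to 5.53). In failing replicate 5, the mean of Wnt signalling was 5.21 (4.52 to 4.8) and that of pericyte and smooth muscle markers 5.77 (5.32 to 5.44). TIMP1 in failing replicate 4 was 8.47 (7.09 to 7.55). Among controls, APOA1 was 5.33 in replicate 3 (3.14 to 3.79), and the mean of NF-kB, cytokine and acute phase genes was 7.13 in replicate 5 (4.36 to 5.18).

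The levels of NPPA and NPPB overlapped between the groups, with control replicates 2 and 3 high and failing replicate 3 low. Exchanged group labels of these libraries were argued against: each library was placed between the control mean (0) and the failing mean (1) using genes called without it, and controls 2 and 3 lay at 0.0125 and 0.321 while failing replicate 3 lay at 0.859. Controls 1 and 4, which have low NPPB, lay at 0.577 and 0.518, nearer the failing mean. A position over 0.5 had been set beforehand as the mark of a wrong label, so these 2 controls passed that mark. Their MYH6, at 1011 and 863 FPKM, lay above that of each failing library (at most 151 FPKM). The cause of their position was not tested. Atrial tissue in controls 2 and 3 may contribute and cannot be told apart from a ventricular rise: the other 4 measured atrial markers had a median log2 ratio of 0.223 (SD 0.838) over the remaining controls, where NPPA had at least 2.89. The markers did not agree: MYL7 was higher in controls 2 and 3 (3150 and 4002 against a median of 1720 FPKM in the other controls). GJA5 was slightly higher (6.81 and 7.20 against 5.86), TBX5 lower (9.27 and 12.9 against 15.6) and MYL4 lower in control 2 and higher in control 3. MYL7 was also high in controls 6 and 7 (4101 and 4024 FPKM), where NPPA was 272 and 57.5 FPKM. The mean log2 level of the 4 markers had a Pearson r with NPPA of -0.137 over the controls and 0.602 over the failing libraries. A difference between donors in ventricular stress also stays open, as untested.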

How the results depend on the processing

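The alternatives without control replicates 2 and 3, without 3 and 5, with a minimum mean of 20 FPKM, with both group medians at 9.05 FPKM or more, and with the set term but without control replicate 5 were chosen after seeing the data. Of the 42 called named genes 25 stayed called in each of the 14 fits that left out 1 library, as did 5 of the 10 called lists. The called share, 4.56% of 7024 genes (320), became 0.0570% in set 1 alone (4 genes) and 0.740% in set 2 alone (52 genes; fewer samples), 3.02% at a minimum mean of 20 FPKM (5.09% of the 4161 genes tested), 2.52% with both group medians at 9.05 FPKM or more (2.85% of the 6202 tested), 2.56% without controls 2 and 3, 3.02% without controls 3 and 5, and 2.26% to 7.13% with 1 library left out, where the cause was not tested. Other thresholds gave 8.90% (adjusted p under 0.1), 0.641% (under 0.01) and 1.99% (at least 2-fold). The filters at no minimum and at 5 FPKM removed no gene and test nothing. Among listed genes and lists the set term changed the calls of XBP1, EGFL7, MYH11, KRT8, the TGF-beta and BMP list and the matrix protease list and no other. Of the called named genes SERPINA3 alone stayed called in set 1, and in set 2 calls ended for WNT9A, HFE2, PI16, CMTM5, HOPX, MYOM2, TNNI3, KCNH2, COL6A3, TIMP1, MMP19, LTBP4, ENO1, CCND1, CCND2, GATA6, HSPB7, KLF2, S100A8, MYL2, CGNL1, CD163 and CD14 (fewer samples). Calls ended without controls 2 and 3 for HFE2, PI16, HOPX, KCNH2, TIMP1, MMP19, LTBP4, ENO1, S100A8 and CGNL1, and without 3 and 5 for HFE2, PI16, COL6A3, TIMP1, MMP19, LTBP4, ENO1, KLF2, CGNL1 and the matrix protease and heat shock lists. With the set term but without control replicate 5 they ended for KCNIP2, TIMP1, KLF2 and the matrix protease, heat shock and lymphatic lists. With both group medians at 9.05 FPKM or more they ended for TIMP1, KLF2, MYL2 and the matrix protease, Wnt and NF-kB lists, and the cell cycle and fibroblast lists passed (medians 0.15 and 0.64, adjusted p = 0.0485 for each; adjusted p = 0.529 and adjusted p = 0.545 with an estimated correlation). Named genes below the limit, and the lymphatic list, which kept under 3 members, have no value at a minimum mean of 20 FPKM or with the limit on both medians. Scaling left the median of all genes within 0.1. The unknown depth limits what can be said of low genes.

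Signs, or for lists the direction of the set test, changed in 73 fits of 20 results. In 0 of them had the value passed the threshold in either fit, and the cause was not tested. Values are log2 fold changes, for lists the median, which can keep its sign where the direction of the set test changed. With array weights they were 0.12 for ADRB1, 0.016 for calcium handling, -0.00403 for p53, -0.018 for immediate early, 0.13 for glucocorticoid and 0.052 for hypoxia genes. Quantile normalization gave 0.21 for glucocorticoid genes. Set 1 gave -1.83 for NPPB, 0.40 for ADRB1, -0.36 for COL1A1, 0.13 for PDPN, 0.069 for calcium handling, -0.045 for hypoxia and -0.065 for pericyte genes. Set 2 gave 0.998 for POSTN, -0.057 for adrenergic, 0.016 for oxidative phosphorylation, -0.028 for citrate cycle, -0.12 for cardiac transcription factor, 0.041 for p53, -0.051 for interferon, -0.030 for MHC class II, 0.25 for glucocorticoid and 0.020 for ribosomal genes. Leaving out members of a second list gave -0.10 for cardiac transcription factors. A minimum mean of 20 gave 0.12 for p53, 0.21 for glucocorticoid and -0.040 for hypoxia genes. Both group medians at 9.05 or more gave 0.089 for p53 and 0.21 for glucocorticoid genes. The set term without control 5 gave -0.012 for p53, 0.16 for immediate early, 0.065 for glucocorticoid and 0.051 for hypoxia genes. Without controls 2 and 3, COL3A1 was 0.12, POSTN 0.33 and the citrate cycle 0.041. Without controls 3 and 5, COL3A1 was 0.26, POSTN 0.20, p53 0.018, immediate early -0.024 and hypoxia -0.035. With 1 library left out, ranges were -0.25 to 0.051 for ADRB1, -0.055 to 0.57 for COL1A1, -0.44 to 0.23 for COL3A1, -0.38 to 0.49 for POSTN, -0.037 to 0.12 for calcium handling, -0.061 to 0.48 for collagens, -0.061 to 0.14 for p53, -0.41 to 0.16 for immediate early, -0.094 to 0.16 for MHC class II, 0.044 to 0.23 for glucocorticoid, -0.24 to 0.042 for hypoxia, -0.14 to 0.042 for ribosomal and -0.19 to -0.010 for pericyte genes.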

Other observations

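The genes in this paragraph were chosen after their values were seen. By limma, VSIG4, a complement receptor of macrophages, was lower in failing hearts (log2 fold change -1.49, SE 0.38), as were LAPTM5 (-1.38, SE 0.29), FCER1G, an immunoglobulin receptor subunit (-1.32, SE 0.24), and CD53 (-1.23, SE 0.21). The transcription factor gene STAT3, which acts downstream of OSMR, fell from 137 ± 80.5 to 45.1 ± 12.4 FPKM (SD, n = 7 each), as did JAK1 (-0.78, SE 0.21), whereas JAK2 rose (1.07, SE 0.25). COL21A1 (1.52, SE 0.36), COL16A1 (1.44, SE 0.33) and COL7A1 (1.07, SE 0.22) rose, but of the 21 genes whose symbols start with COL 3 rose and 1 fell, with a median of 0.12 (camera adjusted p = 0.745). Of 107 families of genes sharing a symbol stem, tested with camera, the stem S before a digit (11 genes, the measured S100 genes with S1PR1 and S1PR3, 4 lower, adjusted p = 0.00326) and the stem CD (28 genes, 6 lower, adjusted p = 0.00402) passed, with adjusted p = 0.576 and adjusted p = 0.980 with an estimated correlation.

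The tests of the macrophage markers, the acute phase genes and the genes at 0 were chosen only after the related values had been seen, while the count over other splits was planned. Of 100 splits of the 14 libraries into 7 and 7, drawn at random with the real one included, 1, the real one, gave as many as 320 genes and the highest other gave 8. So high a count is therefore unlikely by chance alone. The splits cannot tell heart failure from another trait that differs between the 7 and 7 donors.

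In failing hearts 4 of 7 macrophage markers and 4 of 12 NF-kB and acute phase genes fell, and the set tests of both lists were lost with an estimated correlation (adjusted p = 0.415 for each). The log2 differences of the macrophage markers ran from -1.95 to -0.03, a spread larger than under permuted labels (exact permutation p = 0.00408). This spread cannot decide on a lower share of macrophages. Markers that differ in level, or that other cells also make, would fall unequally on the log2(FPKM + 1) scale even from a lower share alone. LYVE1 is also a lymphatic marker. For the acute phase genes, the score, which left out S100A8 and S100A9, fell with rising macrophage score among the 7 controls (Pearson r = -0.876, exact permutation p = 0.00377; Spearman rho = -0.786, exact permutation p = 0.048; r = -0.523 without the 2 libraries farthest out). Within groups and sets without control 5 the r was -0.871 (one-sided permutation p = 0.00842). Among the 7 failing libraries Pearson r was -0.662 (exact permutation p = 0.11). Within groups the score was thus not lower where the macrophage score was lower. That does not settle what caused the difference between groups, so a lower share of macrophages stays open. A changed state of the macrophages and a difference in acute illness between donors may each contribute, and both stay open as untested.

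In control replicate 7, 8 genes other than small RNAs were listed at 0: DNPEP, DES, SPEG, GMPPA, CHPF, OBSL1, STK11IP and SLC4A3. They are all 8 listed genes of one stretch of chromosome 2 in RefSeq order (GRCh38.p14), between DNAJB2 and EPHA4, and DES was between 6007 and 13421 FPKM in the other 13 libraries. A candidate explanation is that the authors' program gave no estimate for this stretch in that library, since 8 of 8 neighbours share the zero. Few cardiomyocytes were argued against, since the 10 cardiomyocyte markers had a mean log2 level of 11.35 there (10.94 to 11.44 in the other controls). Without this library the log2 fold change of DES moved from 1.61 to -0.27 (adjusted p = 0.605 and 0.428), so neither value was past the threshold.

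Control libraries lay farther from their group mean than failing libraries, with a ratio of mean distances of 1.34 (exact permutation p = 0.00291), and 1.25 without control replicate 5 (exact permutation p = 0.00699). Control replicate 5 had the highest mean log2 level of immediate early genes (7.60), of heat shock genes (8.43) and of metallothioneins (7.83) among the 14 libraries.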
